A study of Homo sapiens with 4 samples.

How the data were processed

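Gene expression was compared on 4 spotted 2-colour cDNA arrays of human sequences. Each array held RNA of irradiated HCT116-Clone2 cells in one dye and RNA of unirradiated HCT116-Clone10 cells in the other. Per the labels, Clone2 carried Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4, so the design holds 2 arrays in each dye orientation. RNA from different batches was pooled before labelling, per the labels. Nothing in the labels says that each array had a pool of its own. The p-values therefore measure only the spread between hybridisations, in the main fit those of the same dye orientation, and that spread may be technical.

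The arrays were scanned with ScanArray Express and quantified with QuantArray 3.0, and the data were processed with the Normaliser2 spreadsheet macro, per the labels. The deposited values are log2 ratios of the channels, after subtraction of the sub-array background and a regression on log intensity within each sub-array, per the labels. Per the labels, spots with a signal under 2.5 times the sub-array background, spots under 5% spot intensity and spots with streaks or damage were to be removed. The table used here nevertheless holds a value for each of the 19200 spots on all 4 arrays, so weak or damaged spots could not be told from good ones. No spot intensity or flag was used here, and the signal over background behind a ratio is unknown. The numerator of the deposited ratio is not given in the sources used here. The log2 scale is as stated by the labels. The deposited medians per array were -0.02, 0.00, -0.03 and -0.07 for replicates 1 to 4, and no further centring was applied in the main fit.

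Spots were named through the platform's gene annotation, matched on the spot identifier. Of the 19200 probes, 10914 had 1 gene symbol, 1435 had several and 6851 had none. Entrez identifiers matched the RefSeq gene table of assembly GRCh38.p14 for 10882 of the named probes, and 0 symbols were updated. Probes with the same single symbol were averaged per array, which gave 7498 genes, 2345 of them with more than 1 probe. Probes with no symbol or several were kept as 8286 unnamed features, for 15784 features in all. Control spots could not be recognised in the tables used here and stay among the unnamed features. No genome coordinates were used.

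Whether to turn replicates 3 and 4 was settled by a rule fixed before the data were examined. If the median correlation across features between arrays of opposite dye orientation was under -0.1, the values were read as Cy5 over Cy3 and replicates 3 and 4 were multiplied by -1. The rule assumes that the difference between the RNA pools exceeds the remaining dye effect. It gives an assumed direction only, called likely below, because the correlation is the same whichever dye is the numerator. With Cy3 over Cy5 every sign would reverse. The other reading takes all 4 arrays as deposited and equals the dye term of the fit.

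The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 ratios, with the mean over the 4 turned arrays tested against 0, a dye term for the orientation, and Benjamini-Hochberg adjustment at 5%. The test was two-sided. The residual spread is measured within a dye orientation, so a gene whose orientations differ can have a small p beside a large SD over the 4 arrays. The 35 gene lists were fixed before the data were examined and tested with limma's camera, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. A list needed at least 5 measured members, and all 35 had them. Of the 1225 listed genes, 639 were measured.

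Genes were named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest mean ratios among genes past the threshold with one sign on all 4 arrays. As no gene passed, its fallback applied, which takes the 10 highest and 10 lowest moderated t statistics among genes of one sign on all 4 arrays, as values only. It also takes up to 4 members of each list with the smallest unadjusted p, and 12 genes of the radiation response wherever measured. Only 4 members of the first 6 lists and 2 of each other list were taken up. That narrowing was chosen after the data had been seen, and the rule then covers 102 genes.

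The procedure was tested on simulated data with the spread and dye terms of these arrays, over 15784 features in 20 rounds. For the comparison of irradiated Clone2 with Clone10, the fit recovered 0% of genes set 1.5-fold apart, 1.1% at 2-fold, 63.7% at 4-fold and 86.6% at 8-fold. It made 0.05 calls per round with no gene changed, and 4.72% of its calls were false. A list shifted by 0.5 on the log2 scale was called in 20 of 20 rounds. The simulated features were independent of each other, and no gene outside that list was changed in the list test. On the real arrays neighbouring spots correlated at 0.347. There 17.93% of features had an unadjusted p under 0.05 in limma, against 4.96% in simulated data with no gene changed. The simulated recovery therefore does not give the power for these arrays. The number of arrays limits the precision: the median half-width of the 95% confidence interval over features was 0.44 on the log2 scale, or 1.36-fold.

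Alternatives fixed before the data were examined were the fit without a dye term, the other reading of the direction, median centring, between-array scaling, filters on missing values, each probe alone, robust eBayes, array weights, a size threshold, a size rule with no test, and leaving out each array. Further alternatives were chosen after seeing the data: subtraction of the median of the surrounding 7 by 7 spots, centring of sub-arrays, subtraction of the median of spots at the same row and column over the 48 sub-arrays, and removal of the first row of sub-arrays. Spot positions came from the spot identifiers, which give 12 by 4 sub-arrays of 20 by 20 spots.

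Also after seeing the data, probes of one gene were compared with each other as a check of the names. Genes with exactly 2 probes in different sub-arrays gave 1547 pairs. As a background that keeps the structure of the slide, the same names were set against 65 rearranged layouts, with sub-arrays, rows or columns mirrored or transposed or the spot order changed. None of these was used to rename a spot. Intervals for correlations are bootstrap intervals of 2000 draws, computed with Python 3.11.15 and numpy 2.4.6.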

Results

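HCT116 is a human colorectal carcinoma line, and both cell populations compared here were clones of it. Clone2 is described as resistant to X-radiation, and Clone10 as responding to it much like the parental line. RNA of Clone2 was collected 10 min after a dose of 4 Gy and compared with RNA of unirradiated Clone10 on 4 arrays. The comparison asks which transcripts differed between the irradiated resistant clone and the unirradiated control clone. Clone and irradiation differ together in this design, so their contributions cannot be told apart. All 4 arrays held 19200 values each, with SDs of 0.69, 0.65, 0.58 and 0.90 on the log2 scale for replicates 1 to 4. The share of spots more than 2-fold from equality was 9.5%, 8.78%, 8% and 20.3%.

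Arrays of the same dye orientation correlated across features with a median Pearson r of 0.33, and arrays of opposite orientation with a median of -0.18. These correlations run across features of each array pair, and features are not independent replicates. By the rule fixed beforehand the values were read as Cy5 over Cy3, and replicates 3 and 4 were turned. A positive log2 ratio then stands for a higher level in irradiated Clone2 than in Clone10 only if Cy5 was the numerator. That was assumed and not tested, because the correlations are the same for Cy3 over Cy5, under which every gene and list sign below would reverse. The word likely, as used below for directions, marks this assumption. The labels do not state the numerator, and under the other reading 63 of the 102 named genes had the opposite sign. All directions given for genes and lists below hold only for the first reading with Cy5 as the numerator.

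Gene names rest on the platform annotation, and probes of the same gene hardly moved together. Across the 1547 pairs of probes of one gene in different sub-arrays, Pearson's r of the turned mean was 0.03 (95% bootstrap interval -0.03 to 0.08) and Spearman's rho was 0.02. The 2 probes had the same sign in 50.6% of pairs. The turned mean itself had a reliability of 0.58 between arrays. Of 65 rearranged layouts, 34 gave as high a correlation of the turned mean. For the mean as deposited, which is the other reading, r was 0.06 (95% bootstrap interval 0.01 to 0.11), 52.8% of pairs had the same sign, and 4 of the 65 layouts gave as high a correlation. This measured limit applies to every gene value below.

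**Figure D1:**
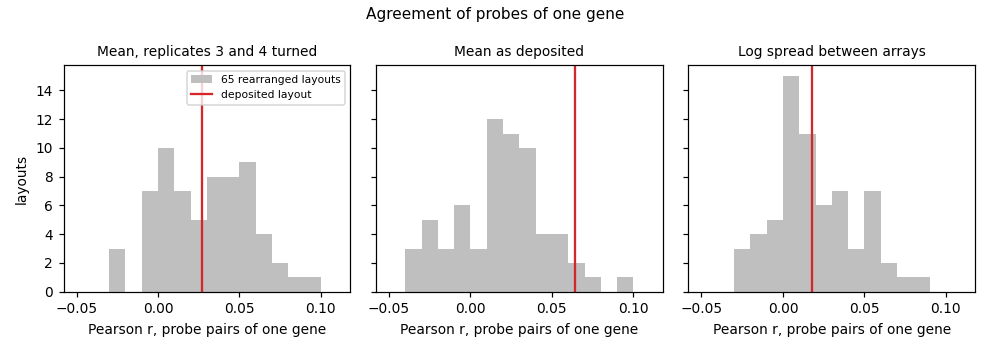
Histograms of Pearson's r between 2 probes of the same gene over 1547 pairs, for 65 rearranged layouts (grey bars, number of layouts on the vertical axis) and the deposited layout (red line). The deposited layout lies at 0.03 for the turned mean, 0.06 for the mean as deposited and 0.02 for the log spread between arrays, within the range of the rearranged layouts in each panel.

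Among the 10 genes with the lowest moderated t and one sign on all 4 arrays, the lowest turned ratios belonged to MGAT1, a glycosyltransferase that starts the building of complex N-glycans, at -2.47 ± 0.85 (log2, SD, n = 4 arrays), to WRAP73 at -2.29 ± 0.41 and to COMMD9 at -1.82 ± 0.82. Among the 10 with the highest moderated t, the highest belonged to ZKSCAN1, a zinc finger protein, at 1.85 ± 1.85, to PVALB, the calcium-binding parvalbumin, at 1.5 ± 0.65 and to ZNF79, another zinc finger protein, at 1.29 ± 0.38. Under the other reading ZKSCAN1 stood at -1.59, PVALB at 0.54, ZNF79 at -0.28, MGAT1 at 0.62, WRAP73 at 0.02 and COMMD9 at 0.71, and each of the 10 genes at either end was smaller by over 1.5 times or of the opposite sign. None of the 15784 features passed Benjamini-Hochberg adjustment at 5% in limma, and the lowest adjusted p was 0.198. At an unadjusted p under 0.05 there were 2830 features, against 789 from chance alone, with 1171 higher and 1659 lower in likely direction. With 1 array left out the count was 1511 without replicate 1, 1417 without replicate 2, 3905 without replicate 3 and 2159 without replicate 4, and the share higher was 41.4% over all arrays but 26.2% without replicate 2 and 29.2% without replicate 1. The same sign on all 4 arrays was seen for 4745 features, or 30.1%, after turning and for 11.6% as deposited. The turning was chosen from the correlations of these same arrays, which raises the first share, so it is no test of a difference. An exact sign-flip test over 4 arrays cannot give a p below 0.125. Under the other reading 1166 features lay below an unadjusted p of 0.05, and 0 passed adjustment. The same choice of turning favours the turned count over this one.

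The other genes among the 10 highest moderated t statistics had ratios near 2-fold. The tightest over arrays was PTPN12, a protein tyrosine phosphatase measured by 3 probes, at 0.97 ± 0.07 (SD, n = 4). That SD follows averaging of its probes, whose single means ran from 0.70 to 1.39. CCDC12 stood at 1.14 ± 0.16, TIMM44, a part of the mitochondrial protein import motor, at 1.05 ± 0.43 and DNAJB5, a co-chaperone of the HSP40 family, at 1.01 ± 0.36. PDE11A, a cyclic nucleotide phosphodiesterase, was at 0.97 ± 0.50, BAG3, a co-chaperone of HSP70, at 0.94 ± 0.32 and MEIS1, a homeobox transcription factor, at 0.85 ± 0.61. Among the lowest, CEP41, a centrosomal protein, stood at -1.44 ± 0.34, RASAL1, a RAS GTPase-activating protein, at -1.38 ± 0.34, MMP24, a membrane-type matrix metalloproteinase, at -1.30 ± 0.36 and KIAA1958 at -1.30 ± 0.48. HSD17B6, a steroid dehydrogenase, was at -1.25 ± 0.18, SUN5 at -1.23 ± 0.81 and ZNF226 at -1.18 ± 0.45. The adjusted p in limma was 0.198 for each of these 20 genes. Several of these values were shared by surrounding spots. After the median of the surrounding 7 by 7 spots was subtracted, 9 of the 10 highest and 5 of the 10 lowest were smaller by over 1.5 times. BAG3 then stood at 0.10, TIMM44 at 0.12, MEIS1 at 0.10, PDE11A at -0.00 and PTPN12 at 0.48.

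**Figure D2:**
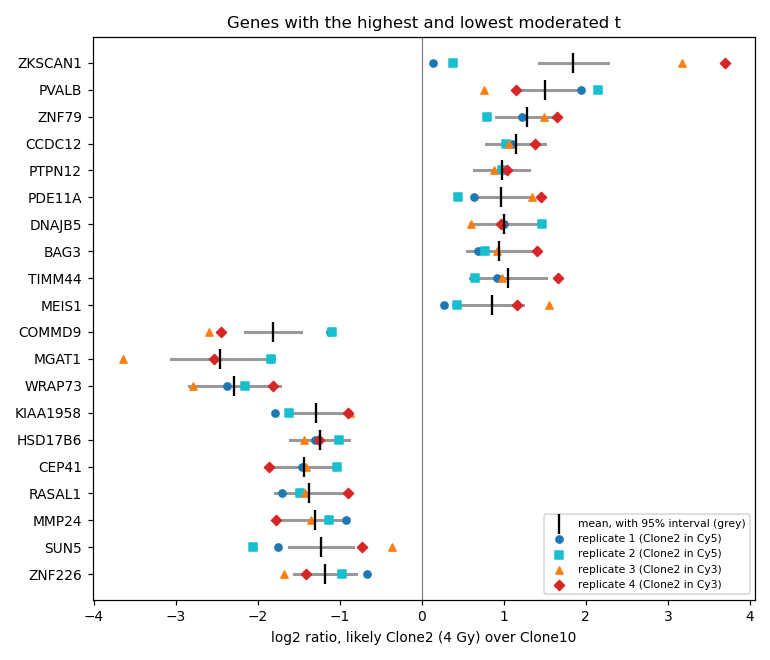
Log2 ratios (horizontal axis, likely Clone2 at 4 Gy over Clone10) of the 10 genes with the highest and the 10 with the lowest moderated t, with 1 symbol per array, the mean as a black bar and its 95% confidence interval from limma in grey. ZKSCAN1 runs from 0.14 and 0.38 on replicates 1 and 2 to 3.18 and 3.70 on replicates 3 and 4, while the 4 values of PTPN12 lie between 0.87 and 1.04.

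The measured p53 target genes did not stand apart as a list at the time sampled. Only 24 of the 49 listed genes were measured, no later time was sampled, and probes of the same gene hardly moved together. The values therefore cannot show whether a p53 response was present or absent. Of 24 measured p53 target genes, 15 had a mean above 0 and 9 below, the median ratio was 0.10 and camera gave an adjusted p of 0.948. CDKN1A, which encodes the cell cycle inhibitor p21, stood at 0.18 ± 0.17 (SD, n = 4). GADD45A, a damage-inducible growth arrest gene, stood at -0.29 ± 0.38, or -0.08 without replicate 3 and -0.50 without replicate 4. The members with the smallest unadjusted p were DDB2, a damage sensor of nucleotide excision repair, at -0.98 ± 0.60, TIGAR, a regulator of glycolysis, at -0.81 ± 0.87, FAS, a death receptor, at -0.58 ± 0.61 and RRM2B, a ribonucleotide reductase subunit, at -0.33 ± 0.38. None passed, either over all features or adjusted over the list alone, where the lowest adjusted p in limma was 0.145. Of the 12 genes fixed for the radiation response, 5 were measured, among them CLU, or clusterin, at -0.11 ± 0.28.

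Immediate early genes, the first transcripts to respond to many stimuli, had 12 of 26 measured members above 0 and 14 below, with a median of -0.06 and an adjusted p of 0.924 in camera. DUSP4, a MAP kinase phosphatase, stood at -0.71 ± 0.36 (SD, n = 4), and NR4A2, an orphan nuclear receptor, at -0.96 ± 0.72. BTG1, an antiproliferative gene, was at 1.26 ± 1.34 but at 0.64 without replicate 4, and DUSP6, another MAP kinase phosphatase, at -0.38 ± 0.22. Adjusted over the list alone, 0 members passed.

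The DNA repair lists gave no call either. Of 10 measured genes of non-homologous end joining, 8 lay below 0, with a median of -0.09. XRCC5, the Ku80 subunit that binds broken DNA ends, stood at -0.44 ± 0.50 (SD, n = 4), LIG3, a DNA ligase, at -0.27 ± 0.11, PARP1, the poly(ADP-ribose) polymerase, at -0.29 ± 0.25, TP53BP1, a double-strand break response protein, at -0.22 ± 0.18, and PRKDC, the catalytic subunit of DNA-dependent protein kinase, at -0.04 ± 0.43, with a sign that differed with the array left out. Homologous recombination had 7 of 15 members above 0 and a median of -0.02, with WRN, the Werner helicase, at 0.57 ± 0.16 and RAD50 at -0.22 ± 0.14. Its nuclease genes EME1 and MUS81 stood at -0.32 ± 0.27 and -0.67 ± 0.86, the latter at -0.26 without replicate 4 and -1.09 without replicate 3. Excision and mismatch repair had 11 of 19 members above 0 and a median of 0.04, and ERCC1, an endonuclease subunit, stood at -0.52 ± 0.33, ERCC2, a helicase of TFIIH, at -0.74 ± 0.76, or -0.40 without replicate 4, and SMUG1, a uracil glycosylase, at -0.52 ± 0.48. Damage checkpoint signalling had 5 of 14 members above 0 and a median of -0.21. In that list CDC25A, a phosphatase that drives cell cycle entry, was at -0.62 ± 0.39, RAD1 at 0.43 ± 0.18 and CDC25C at 0.41 ± 0.49. RAD18 was at -0.79 ± 0.84, or -0.34 without replicate 1 and -1.24 without replicate 2. Camera's adjusted p was 0.924 for non-homologous end joining, excision repair and checkpoint signalling and 0.948 for homologous recombination, and adjusted over the list alone 0 members passed in any of the 4.

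The 2 lists with an unadjusted p under 0.05 in camera lay in opposite directions. Growth factor signalling had 16 of 26 measured members below 0 and a median of the 4-array means of -0.26, with an adjusted p of 0.694 in limma's camera. Its medians on the single arrays were closer to 0, at -0.02, -0.18, -0.03 and -0.20 on replicates 1 to 4. Its members included FGFR3, a fibroblast growth factor receptor, at -1.17 ± 0.45 (SD, n = 4). EGFR, the epidermal growth factor receptor, stood at -1.61 ± 2.27, with -3.79 and -3.31 on replicates 1 and 2 but 0.67 and -0.00 on replicates 3 and 4. Its unadjusted p in limma of 0.000574 rests on the dye term, which takes up that difference between orientations. The unfolded protein response, the stress programme of the endoplasmic reticulum, had 13 of 18 members above 0 and a median of 0.19, also with an adjusted p of 0.694 in limma's camera. HERPUD1, of endoplasmic reticulum-associated degradation, stood at 0.38 ± 0.45 and XBP1, a transcription factor of that response, at 0.31 ± 0.49. With an estimated correlation the adjusted p was 0.956 for both lists, and under the other reading the median of the unfolded protein response was -0.14 and that of growth factor signalling was 0.03, so both changed sign.

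Cell cycle and cell death lists lay on both sides of 0. G1/S and DNA replication had 17 of 27 members above 0, with MCM7, of the replicative helicase, at -0.77 ± 0.64 (SD, n = 4) and RFC1, of the clamp loader, at -0.59 ± 0.34. G2/M and mitosis had 7 of 21 members above 0, with BUB3, a spindle checkpoint protein, at -0.81 ± 0.68 and CENPF, a kinetochore protein, at -0.56 ± 0.09. Pro-apoptotic genes had 8 of 16 members above 0, with CASP10, an initiator caspase, at -1.33 ± 1.32 and AIFM1, the apoptosis-inducing factor, at -0.72 ± 0.31. Survival genes had 11 of 22 above 0, with MTOR, the growth-regulating kinase, at -1.05 ± 0.62 and BAG3 at 0.94 ± 0.32. Camera's adjusted p ranged from 0.694 to 0.975 over all 35 lists. Adjusted over the list alone, 8 entries in 4 lists passed 5% in limma, 3 in growth factor signalling, 2 in pro-apoptotic genes, 2 in survival genes and 1 in heat shock and chaperones. None of them passed over all features tested. BAG3 counts in both of the last 2 lists, and the small p of EGFR and of CASP10, at -0.08 and -0.37 on replicates 1 and 2 but -2.07 and -2.81 on replicates 3 and 4, rests on the dye term. Of the 8 entries, 3 passed again without the dye term, with neither EGFR, CASP10 nor AIFM1 among them. After the local median was subtracted 2 passed again, EGFR and FGFR3, without BAG3. After row and column medians were subtracted 4 did, CASP10, EGFR, INSR and FGFR3. Without the first row of sub-arrays only 2 did, AIFM1 and CASP10, and no growth factor entry, BAG3 or MTOR. Some genes had no value without that row, so an entry could also drop out for that reason. Under the other reading 2 passed again, CASP10 and EGFR. The number of entries was 0 without replicate 1, 3 without replicate 2, 29 without replicate 3 and 1 without replicate 4.

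Stress and inflammatory lists behaved likewise. Heat shock and chaperones had 10 of 19 members above 0, with HSPB1, the small heat shock protein HSP27, at -0.46 ± 0.17 (SD, n = 4). NF-kappaB pathway and targets had 11 of 20 above 0, with the chemokine CCL2 at -1.05 ± 0.47 and the cytokine TNF at 0.64 ± 0.60. Antioxidant and detoxification genes had 18 of 35 above 0, with GPX1, a glutathione peroxidase, at 0.47 ± 0.06 and GCLM, of glutathione synthesis, at -0.95 ± 0.72. Metallothioneins had 2 of 5 above 0, with MT1G at -0.55 ± 0.73 and MT1H at -0.56 ± 0.84. The latter was at -0.17 without replicate 4 and -0.94 without replicate 3. Interferon-stimulated genes had 11 of 22 above 0, with UBE2L6, a conjugating enzyme for ISG15, at -0.70 ± 0.50 and IFIT3 at -0.50 ± 0.36. MHC class I and antigen processing had 5 of 6 above 0. B2M, the light chain of class I molecules, stood at -0.33 ± 0.66, or -0.07 without replicate 4 and -0.60 without replicate 3. PSME1 stood at 0.33 ± 0.54, or 0.03 without replicate 2 and 0.63 without replicate 1. Camera's adjusted p was 0.924 or higher for each of these lists.

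Among metabolic and housekeeping lists, hypoxia and glycolysis had 15 of 21 members below 0 and a median of -0.14. PFKL, a phosphofructokinase, stood at -0.71 ± 0.39 (SD, n = 4) and EGLN1, an oxygen-sensing prolyl hydroxylase, at -0.58 ± 0.19. Oxidative phosphorylation had 19 of 37 above 0, with SDHC of complex II at -1.10 ± 1.03 and ATP5PD of ATP synthase at 0.60 ± 0.18. Of 40 cytosolic ribosomal protein genes 17 lay above 0, with RPL39 at -1.06 ± 0.59 and RPS21 at 0.72 ± 1.30. Translation factors had 9 of 18 above 0, with EIF2S3 at 0.63 ± 1.01 and EIF3B at -0.45 ± 0.32. The proteasome list had 9 of 20 above 0, with PSMD10 at -0.97 ± 0.59 and PSMC4 at -1.25 ± 0.93. Spliceosome and RNA-binding proteins had 12 of 27 above 0, with SNRPA at -0.76 ± 0.71 and U2AF2 at -0.61 ± 0.29. Histones had 3 of 6 above 0, with H2BC21 at 0.90 ± 1.15 and H1-2 at -0.50 ± 0.69. The latter was at -0.20 without replicate 4 and -0.81 without replicate 3. Cholesterol and lipid synthesis had 6 of 16 above 0, with FADS2 and SCD, both fatty acid desaturases, at -0.69 ± 0.25 and -0.95 ± 0.94, the latter at -0.52 without replicate 4. Ubiquitin and SUMO conjugation had 10 of 21 above 0, with UBE2A at 0.52 ± 0.34, and drug transporters had 6 of 11, with ABCB1, the P-glycoprotein gene, at 0.50 ± 0.21 and ABCB6 at -0.63 ± 0.41.

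Lists tied to the tissue of origin and to other cell types also gave no call. Wnt targets and intestinal stem markers had 9 of 13 members below 0, with AXIN2, a feedback inhibitor of Wnt signalling, at -0.57 ± 0.13 (SD, n = 4) and CLDN1, a tight junction protein, at -1.08 ± 0.57. Colon epithelial differentiation had 8 of 12 below 0, with TFF3, a goblet cell peptide, at -0.49 ± 0.15 and DPP4 at -0.39 ± 0.72. Adhesion and mesenchymal genes had 16 of 31 above 0, with ZEB2 at -0.45 ± 0.24 and PLAU at -0.48 ± 0.80. Fibroblast and stromal markers had 7 of 16 above 0, with PDGFRA at -1.62 ± 2.20, or -0.66 without replicate 1 and -2.57 without replicate 2, and PDGFRB at -0.31 ± 0.28. Leukocyte markers had 9 of 15 above 0 and a median of 0.14, with CD37 at 1.5 ± 1.41 and FCER1G at 0.34 ± 0.32. Endothelial and erythroid markers had 6 of 15 above 0, with KDR at -0.54 ± 0.37 and ESAM at -0.43 ± 0.24, and neural markers had 5 of 12, with MAPT at -0.82 ± 0.38 and NEFL at -0.48 ± 0.27.

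**Figure D3:**
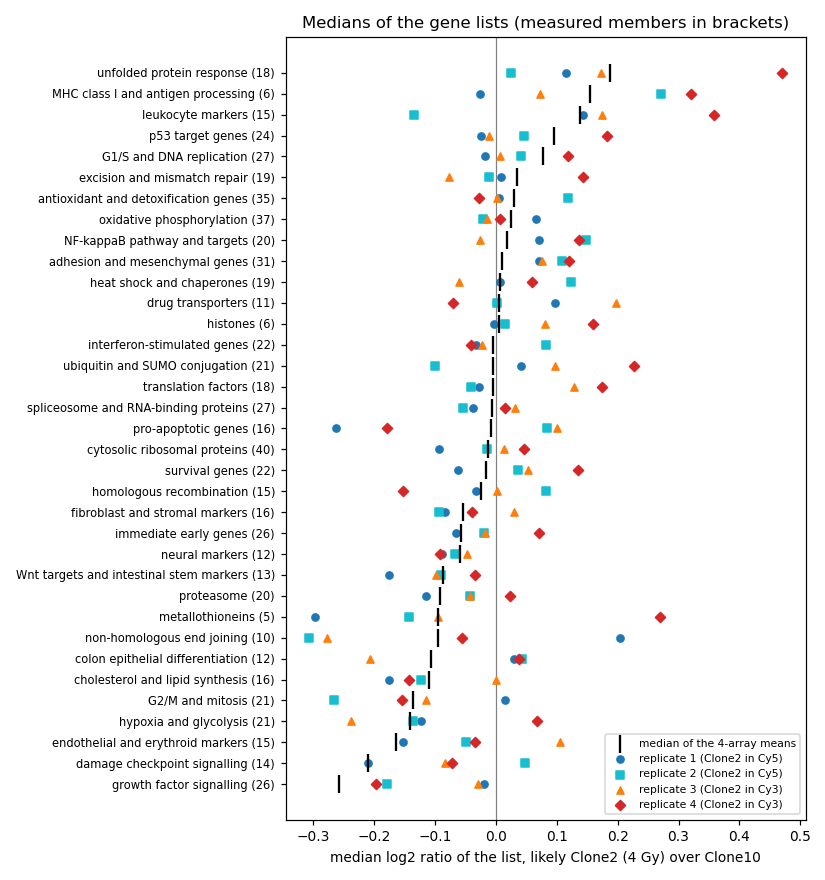
Median log2 ratio (horizontal axis, likely Clone2 at 4 Gy over Clone10) of each of the 35 gene lists on each array (coloured symbols) and over the 4-array means (black bars), with the number of measured members in brackets. The medians over the means run from -0.26 for growth factor signalling to 0.19 for the unfolded protein response, and 0 of the 35 lists passed adjustment in camera.

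The dye term of the same limma fit asked how far each feature differed between the dye orientations. No feature passed adjustment, the lowest adjusted p was 0.359, and 1166 features had an unadjusted p under 0.05. The SD of the dye term over features was 0.34, against 0.44 for the turned mean, read as the difference between irradiated Clone2 and Clone10. The arrays were turned because opposite orientations correlated negatively, which itself makes the second SD the larger. The 2 SDs are therefore no test of which effect exceeds the other. The term was -1.94 for EGFR, -1.59 for ZKSCAN1 and 1.11 for CASP10, so each of these genes differed strongly between orientations. They were not the only ones, as it was -1.12 for RPS21, -0.93 for H2BC21, -0.85 for EIF2S3 and 0.82 for SDHC. For RPS21, H2BC21 and EIF2S3 the dye term was larger in size than the turned mean.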

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

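The tests of chance signs, of gene expression, of the reading of the direction, of touching spots across borders and of the probe names were chosen or revised only after the result was seen, and the tests that subtract local or row and column medians or set spots of the same row and column side by side were settled before their results. Of 140 sets of 4 values tested, 8 had 1 array far from the other 3 by Dixon's test, and chance flags about 1 in 20. Replicate 4 had 20.3% of spots over 2-fold, against 8% to 9.5% on the others. On that array 4 single genes stood apart as well.

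The 4 genes were MUS81 at -1.96 against -0.30 to -0.20 on the others, ERCC2 at -1.88 against -0.52 to -0.27, MT1H at -1.80 against -0.28 to 0.02, and CDC25A at -0.0369 against -0.84 to -0.81. CLDN1 stood apart on replicate 1, at -1.93 against -0.88 to -0.74. The median of interferon-stimulated genes was 0.0826 on replicate 2 against -0.04 to -0.02, and that of colon epithelial differentiation was -0.21 on replicate 3 against 0.03 to 0.04.

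More features lay below an unadjusted p of 0.05 than chance alone gives, 2830 against 789. After the local median was subtracted 2468 features lay below 0.05, 1659 of them among the 2830 with the same sign. After row and column medians were subtracted it was 2413, 1847 of them among the 2830. Neither subtraction on its own brought the count near the 789 from chance. They were not applied together, and whether either removed every effect of place was not tested, so the counts cannot exclude place as the source. Without the dye term the real pattern of array signs gave 2535 features, the highest other pattern gave 718, and 1 of the 8 patterns reached the real count, but 8 patterns are too few for a share under 0.05, and the real pattern was itself read from the correlations of these arrays. A difference in gene expression predicts that probes of one gene move together, yet their correlation was 0.0267, and this test stays open because it assumes that the names belong to the spots (as first written, it would have excluded expression, with an upper bound of 0.0804 under 0.1). The reading in which the deposited values already run one way gave a correlation higher by 0.0375 (95% interval -0.0371 to 0.113), so it cannot be told apart from the reading used here, and the effects of clone and of irradiation stay confounded in either.

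Neighbouring spots within a sub-array had similar turned means, with r = 0.347 over 36451 pairs across spots. A place effect on the slide is consistent with spots that touch across a sub-array border, which correlated at 0.142 (95% interval 0.089 to 0.193) once each kind of border was centred. The version of that test written before the result pooled both kinds of border and gave 0.0449, with an upper bound of 0.0962 below its limit of 0.1, which would have excluded a local effect. That limit was wrong because pooling fell below both parts, 0.21 for borders within rows and 0.0966 within columns. A shared source plate or place within the sub-array is also consistent with the data, since spots of the same row and column in touching sub-arrays correlated at 0.202, and no biological explanation of the pattern was tested.

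Probes of one gene hardly moved together. If the names did not belong to the deposited rows, the correlation under the deposited layout would lie within those of rearranged layouts, and it did for each of 3 measures. For the turned mean 34 of 65 layouts gave as high a correlation and for the log spread between arrays 31, but for the mean as deposited only 4 did, with r = 0.0642 (95% interval 0.0144 to 0.113), which leans toward the names. No layout reached a correlation above 0.0929, so none of those tried restored agreement between probes. Probe names that do not belong to these rows therefore remain an open candidate explanation, neither shown nor excluded, beside spotted cDNAs that do not report their annotated gene or ratios set mainly by place and plate, and the biological reading, that probes of one gene measure different transcripts, was not tested.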

How the results depend on the processing

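No feature, no list and no dye term passed 5% under any alternative that ran a test, and the lowest adjusted p of a feature was 0.0977, without replicate 3. The count of features below an unadjusted p of 0.05, 2830 in the main fit, was 1166 under the other reading of the direction and ranged from 1417 to 3905 when 1 array was left out. It was 1511 without replicate 1, and 1417 without replicate 2. The share of these features that lay higher was 41.4%, but 29.2% without replicate 1, 26.2% without replicate 2 and 28.1% under the other reading. Under the alternatives to scale, dye term, variance and slide position it lay between 2413 and 3444, the last of 19200 probes each tested alone. The size rule with no test, which takes 1 value per dye orientation, kept 2093 features at least 1.5-fold apart, 705 higher and 1388 lower. As deposited it kept 954, with 175 higher and 779 lower. With 1 array left out, the residual spread comes only from the dye orientation that still holds 2 arrays. The array left alone in its orientation then weighs as much in a gene's value as those 2 together. The leave-one-out counts therefore rest on different pairs of arrays. The cause of the differences between settings was not otherwise tested. For the direction of the arrays, the median correlation of -0.18 was -0.23 with Spearman's rho, -0.14 after the local median and -0.19 after centring sub-arrays. Centring whole arrays cannot move it. Of the 102 named genes, 63 had the other sign under the other reading, and 97 kept their sign under each other alternative that gave them a value (only 86 had one without the first row of sub-arrays). The exceptions were CLU, DUSP6, PDE11A, PLAU and PRKDC. Leaving out 1 array moved 24 of the 102 by over 1.5 times: NR4A2, BTG1, DUSP6, XRCC5, PARP1, TP53BP1, MUS81, ERCC2, SMUG1, CDC25C, RAD18, TNF, MT1H, B2M, PSME1, H1-2, SCD, ABCB6, PDGFRA, PDGFRB, CDKN1A, GADD45A, PRKDC and CLU. Some of these alternatives, those on slide position and the recount of list members, were chosen after seeing the data. Both filters on missing values gave no separate result because no value was missing. Each array held RNA of both clones, so its ratio is already a paired comparison, and no further pairing was used. Signal over background is unknown here, so weak spots limit the ratios to an unknown degree.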

Other observations

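The first test was written before its result was seen, with shuffled probe names as chance, and was revised afterwards to use rearranged layouts. Of 2345 genes with more than 1 probe, 97 had the same sign in every probe on all 4 arrays, 58 higher and 39 lower in likely direction. Among them were PTPN12 at 0.97 ± 0.07 (log2, SD, n = 4), DDR2, a collagen receptor kinase, at -1.23 ± 0.35, and SEMA3A, a secreted guidance factor, at -0.93 ± 0.38. DDR2 and SEMA3A were chosen after their values were seen. Shuffled names gave a median of 76 such genes (95% range 61 to 92), and 5 of 1000 shuffles gave as many. Rearranged layouts, which keep the slide's structure, gave a median of 86 and a range of 69 to 107, and 10 of 65 gave as many. The hypothesis that more genes than chance have concordant probes was therefore not borne out by the 97 genes.

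The first of the 12 rows of sub-arrays stood apart from the others. In it 33.0% of features with a single probe had an unadjusted p under 0.05 in limma, against 12.8% to 22.4% in the other 11 rows, and the median ratio was -0.36.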
